A study of Caenorhabditis elegans with 2 samples.

How the data were processed

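The series held chromatin immunoprecipitation followed by sequencing (ChIP-seq) of HND-1 in Caenorhabditis elegans early embryos. HND-1 is the worm's Hand protein, a basic helix-loop-helix transcription factor with known roles in body wall muscle and somatic gonad precursors. Per the labels, the worms were of strain OP573, which is mutant for unc-119 and carries the transgene wgIs573 with HND-1 fused at its C-terminus to GFP. An antibody against GFP recovered the protein, and mixed-sex embryos were taken 1.5 h after synchronization by bleaching. The 2 samples were the biological replicates of 1 group, so the design gave no comparison between conditions.

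Per the authors' file listing, the deposited lists were regions in narrowPeak format on the builds ce10 and ce11. For each build there was a list from replicate 1, a list from replicate 2 and a list made from both replicates together. Each of these held 30000 regions, described as peaks and background for an analysis of the irreproducible discovery rate (IDR), which keeps regions ranked alike by both replicates. The fourth list per build held the peaks that passed the authors' IDR threshold, and is called the thresholded list here. The signal value of each region was the authors' own, from their peak caller, and its scale was not stated. It was used to rank and describe regions, to correlate the replicates and to set the lists of both builds side by side, without rescaling. The deposited −log10 q values were the caller's as well, and reached at most 1.85 in the pooled ce11 list. The listing gave 1 control per list. The aligner, the peak caller, the IDR threshold and the sequencing depth are not given in the sources used here. The precision behind a region's signal is therefore unknown, and the intervals given for shares cover counting of regions only. Because the lists end at a fixed length, a locus with no region had a signal below that list's floor and need not be free of binding. Signal tracks and alignments were not used here.

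The thresholded ce11 list was found to be the 562 strongest rows of the pooled ce11 list by signal, and the thresholded ce10 list the 767 strongest rows of the pooled ce10 list. Coordinates are ce11, 1-based, and were set against the WBcel235 assembly and its Ensembl gene annotation, which is the same build. The ce10 lists entered by counts and by their own coordinates only, with no conversion between builds. For shifts of ce10 regions the ce11 chromosome lengths were used.

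The choices below were made before the data were examined unless stated otherwise. For agreement between replicates, the strongest 562 regions of each replicate were compared. A region matched when a summit of the other replicate lay within 200 bp, and chance was measured by 1000 circular shifts along each chromosome (one-sided). A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene. Shares of thresholded peaks in these windows were compared with the lower-ranked 15000 pooled regions by Fisher's exact test (two-sided). The same test was used for summits within 200 bp of tRNA, snRNA, snoRNA and rRNA genes. Peaks per chromosome were compared with the distribution of the pooled regions by exact binomial tests (two-sided) with Benjamini-Hochberg adjustment over 7 chromosomes. E-boxes, the CANNTG sites that basic helix-loop-helix proteins bind, were counted within 50 bp of each summit. They were compared with the mean of windows of the same size centred 300 bp to each side, by a sign-flip permutation test with 100000 draws (two-sided). The 10 E-box classes merge each word with its reverse complement and were adjusted together. All 2080 6-mers, merged in the same way, were tested by the exact McNemar test against 1 flank per peak, with Benjamini-Hochberg adjustment. For 17 gene lists, the share of genes with a thresholded summit in the promoter window was compared with the other genes. The background was the 7163 protein-coding genes with any pooled region in that window, the test was Fisher's exact test (two-sided), and adjustment ran over the 17 lists. Wilson intervals at the 95% level are given for shares, and conditional 95% intervals for odds ratios of gene lists.

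The text names the 25 strongest thresholded peaks, members of the fixed lists with a thresholded peak in the promoter window (at most 6 per list, by signal), 7 fixed loci (hnd-1, unc-119, hlh-1, unc-120, pal-1, ehn-3 and hlh-2), the 5 most significant 6-mers and all 10 E-box classes. Anything else named is said to have been chosen after its values were seen. Peaks near tRNA, snRNA, snoRNA or rRNA genes, and mitochondrial peaks, were set aside as alternatives chosen after seeing the data. Other alternatives covered matching distances, list lengths, windows, backgrounds, the build, the stronger peaks alone and each replicate alone. With 2 replicates, no alternative could leave out a replicate from the comparison of the replicates themselves.

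The tests were tried on simulated data. For the comparison of replicates, 300 regions planted as shared among 562 gave 300 matches. Planted summits were moved by at most 100 bp and so had to match within 200 bp. This trial therefore checks the counting only. For E-boxes, 3 of 50 sets of 562 lower-ranked regions had a permutation p under 0.05, and CAGCTG written into 100 centres gave an excess of 95 centres over the flanks. For 6-mers, at most 1 of 2080 words was called in any of 10 such sets, and the planted word came out at place 1. The lower-ranked regions were not matched to thresholded summits in base content or in identical tRNA gene copies. These trials therefore do not give the error rate of the E-box and 6-mer tests on the thresholded peaks. For the gene lists, 5 of 100 random sets of targets among 7163 genes gave any call, and 12 muscle genes made targets gave a Fisher's exact adjusted p of 6.08e-07. For chromosomes, 7 of 200 random sets of 562 regions gave any call. For promoters and for non-coding RNA genes, 6 and 8 of 200 sets of 562 lower-ranked regions had an exact p under 0.05. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.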

Results

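The binding of GFP-tagged HND-1 was profiled in early embryos of Caenorhabditis elegans, in 2 biological replicates immunoprecipitated with an antibody against GFP. The pooled list held 30000 regions with signals from 28.8 to 2976, and 562 of them passed the authors' IDR threshold, with signals of at least 126. These thresholded peaks had a median width of 404 bp and covered 195 kb of the ce11 genome. Sequencing depth is not given in the sources used here, and the signal is the authors' own value on an unstated scale, so no mean of signals across replicates was formed.

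The first question was how far the replicates found the same sites. Of the 562 strongest regions of replicate 1, 414 (73.7%) had a summit within 200 bp among the 562 strongest of replicate 2, and 416 (74.0%) did so in the other direction. Circular shifts gave 1.35% and 1.38% on average, with a permutation p of 0.000999 each, the smallest that 1000 shifts can give. Regions near tRNA, snRNA, snoRNA or rRNA genes were matched most often, in 233 of 249 cases (93.6%) for replicate 1, whereas the regions away from such genes were matched in 181 of 313 cases (57.8%). For replicate 2 the corresponding values were 233 of 269 (86.6%) and 183 of 293 (62.5%). The difference between both kinds of region had a Fisher's exact p of 6.97e-24 for replicate 1 and 3.67e-11 for replicate 2, in a division chosen after seeing the data. Further down the lists agreement was lower, at 36.4% of the strongest 5000 regions and 33.8% of the strongest 10000, against 2.42% and 4.50% under shifts. Of the 562 thresholded peaks, 558 had a region in both replicate lists, and 412 ranked among the strongest 562 in both. The thresholded list was itself chosen from the same 2 replicates by strength and agreement. These counts and the correlation of the replicates are therefore no independent measure of agreement. Across these 558 peaks, which are not independent replicates, Spearman's rho of the replicates' signals was 0.748. It was 0.904 for peaks near the non-coding RNA genes and 0.535 for the others. Peaks near these genes also ranked higher, at medians of 214.5 and 182.5 in replicates 1 and 2, against 318.5 and 384.5 for the others. Regions close to the cut at rank 562 can lose a match by a small change in rank. Rank was not controlled for, so the differences in matching and in rho cannot be assigned to the kind of gene.

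**Figure D1:**
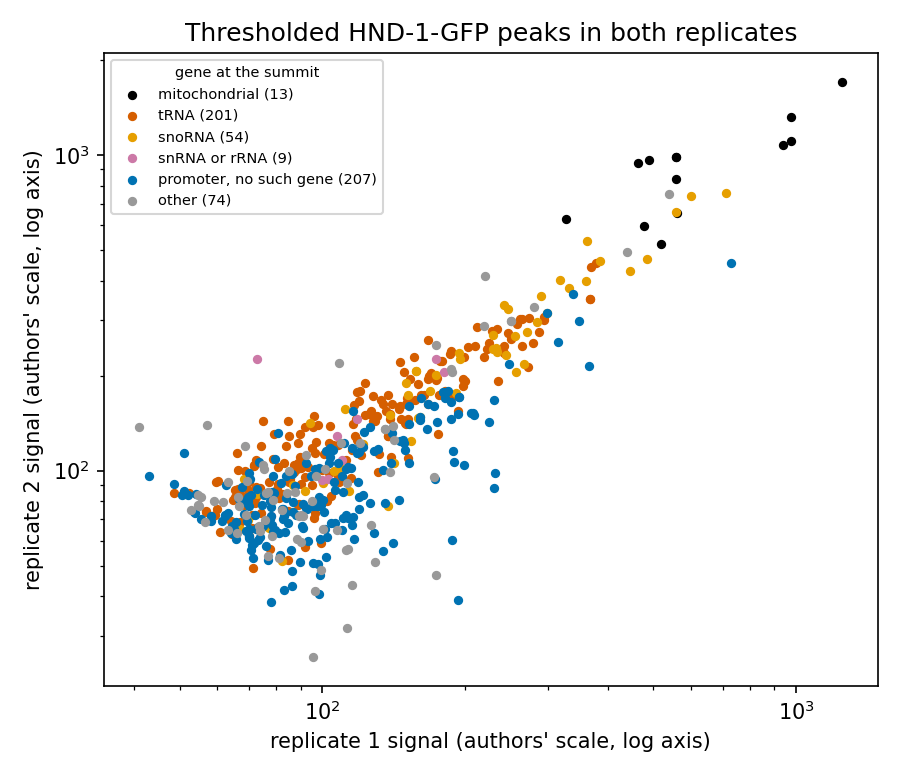
Signal of each thresholded peak in replicate 1 (x axis) and replicate 2 (y axis), both on the authors' scale and on log axes, coloured by the kind of gene at the summit. The 558 peaks with a region in both replicates are drawn, and the black mitochondrial points lie at the top right.

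The strongest peaks lay in mitochondrial DNA and at small nucleolar RNA genes. Of the 25 strongest, 12 were mitochondrial, 8 lay within 200 bp of a snoRNA gene (snoRNAs guide the modification of ribosomal and spliceosomal RNA), 2 at tRNA genes and 3 elsewhere. The highest signal, 2976, had its summit at M:12458, in a coding exon of WBGene00010967, followed by M:2190 in ND1 (2411) and M:6081 in COX3 (2170), which encode subunits of the respiratory chain. These held ranks 1, 2 and 3 in both replicates. In all, 15 thresholded peaks covered 5719 bp of the 13794 bp mitochondrial genome (41.5%). Whether the mitochondrial peaks reflect binding of HND-1 was not tested, and their rank alone does not show it. The strongest nuclear peak was at V:12303443-12303845, over the snoRNA genes C51F7.3 and C51F7.4 within the protein-coding gene frm-7, with a signal of 1463 and ranks 6 and 9 in replicates 1 and 2. The peak at I:8259335-8259751, intergenic and next to the snoRNA gene ZK265.10, lay in the promoter window of sre-23 and had a signal of 1342. The peak at II:11960633-11961019, near the snoRNA gene W03C9.9, had a signal of 1224. Intronic peaks at snoRNA genes lay in pxn-1 (V:8500398-8500725, signal 957, snoRNA gene ZK994.7) and cutl-18 (V:11314060-11314410, signal 875, snoRNA gene T03F7.8). The remaining snoRNA sites in this set were T06C12.16 on V (signal 892), T02E1.9 on I (845) and T19B4.8 on I (759), all intergenic. The tRNA genes in this set were WBGene00000308 on X (X:13665398-13665773, signal 835) and WBGene00022955 within cye-1, the gene for cyclin E (I:6781655-6781981, signal 805). The remaining 3 sites were the promoter window of K12H4.5 (III:8043784-8044157, signal 1182), an intergenic site 4967 bp from the 5′ end of nas-30 (I:933361-933675, signal 1121) and the microRNA gene mir-51 (IV:11025872-11026402, signal 928).

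Thresholded summits lay near genes for tRNA, snoRNA and snRNA more often than lower-ranked regions did. Of the 562 summits, 205 (36.5%, Wilson interval 32.6% to 40.5%) lay within 200 bp of a tRNA gene, against 59 of 15000 lower-ranked regions (0.393%, Fisher's exact adjusted p = 9.05e-255). For snoRNA genes the numbers were 54 summits (9.61%) and 38 regions (0.253%, exact adjusted p = 5.34e-54). For snRNA genes, whose RNAs act in splicing, they were 10 and 13 (exact adjusted p = 3.65e-09), for rRNA genes 3, all of them mitochondrial, and 1 (0.000213) and for microRNA genes 6 and 26 (0.000878). The tests of microRNA genes and of other annotated non-coding RNA genes (192 summits against 792 regions, exact adjusted p = 5.00e-92) were added after seeing the data. All 4 planned classes together took in 270 summits (48.0%) against 111 regions (0.740%), an odds ratio of 124. In the strongest 562 regions of each replicate the share was 44.3% and 47.9%, or 46.1% ± 2.52 (SD, n = 2). Seen from the genes, 223 of 634 tRNA genes (35.2%), 55 of 346 snoRNA genes (15.9%) and 8 of 129 snRNA genes (6.20%) had a thresholded summit within 200 bp. The share near these genes fell with rank, from 73.0% of the 100 strongest pooled regions to 33.7% at ranks 251 to 562 and 11.6% at ranks 563 to 1000.

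**Figure D2:**
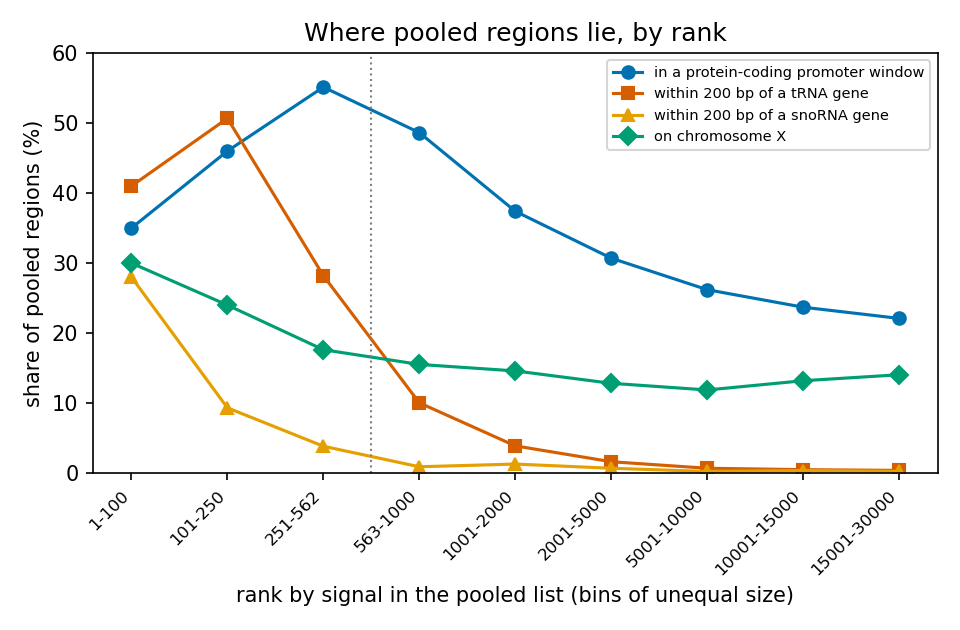
Share of pooled regions (y axis, percent) in a protein-coding promoter window, within 200 bp of a tRNA or a snoRNA gene, or on chromosome X, in bins of rank by signal (x axis, bins of unequal size). The dotted line marks the end of the thresholded peaks at rank 562. The tRNA share goes from 41.0% in the first bin to 0.393% in the last, and the promoter share peaks at 55.1% at ranks 251 to 562.

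The second large class of peaks lay in promoters of protein-coding genes. A promoter window held 276 of the 562 summits (49.1%, Wilson interval 44.997% to 53.2%), against 3315 of 15000 lower-ranked regions (22.1%), an odds ratio of 3.40 (Fisher's exact p = 6.68e-43). With windows of all annotated genes, non-coding ones included, the share was 90.6%, higher than among lower-ranked regions (Fisher's exact p = 9.50e-165). These windows cover more of the genome, and the share of lower-ranked regions in them is not given here. The 90.6% should therefore not be set against 22.1%. After peaks near tRNA, snRNA, snoRNA or rRNA genes were set aside, the share in protein-coding promoter windows was 214 of 292 (73.3%, exact p = 2.77e-75). Among the peaks near such genes it was 62 of 270 (22.96%, exact p = 0.712). By annotation, 280 summits were intergenic (49.8%, against 35.8% of lower-ranked regions), 158 lay inside one of the non-coding RNA genes (28.1%, against 0.207%) and 89 in introns (15.8%, against 39.8%). Coding exons held 20 (3.56%, against 18.3%), 5′ UTRs 12 (2.14%, against 1.74%) and 3′ UTRs 3 (0.534%, against 4.11%). Fisher's exact test with adjustment over these 6 kinds called all but the 5′ UTRs (adjusted p = 0.510 there, and at most 5.08e-07 for the others).

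Chromosome X carried more thresholded peaks than its share of pooled regions, 121 against 76.5 expected, a ratio of 1.58 (exact binomial adjusted p = 9.61e-07). Mitochondrial DNA carried 15 against 0.300 (exact adjusted p = 4.78e-20). Chromosomes I and V carried fewer, with ratios of 0.828 and 0.766 (exact adjusted p = 0.0331 each). For II, III and IV the ratios were 0.910, 1.02 and 0.887, with exact adjusted p-values of 0.477, 0.865 and 0.400. Chromosome X also holds 276 of the 634 annotated tRNA genes (43.5%). Among peaks near tRNA, snRNA, snoRNA or rRNA genes the ratio for X was 2.45 (90 peaks against 36.7, exact adjusted p = 9.59e-16). Among the 292 other peaks it was 0.780 (31 against 39.7, exact adjusted p = 0.343), and no nuclear chromosome was called. Against chromosome length instead of pooled regions, 6 chromosomes were called: I was above expectation, at 1.36 (exact adjusted p = 0.00138), III also passed at 1.23 (0.0373) and IV at 0.755 (0.0113), and X, V and mitochondrial DNA kept their calls. The deficit of I against pooled regions was not called in either replicate alone (ratios of 0.940 and 0.953) or on ce10 (0.945, exact adjusted p = 0.563), and that of V not in replicate 1 alone (0.787, exact adjusted p = 0.0653); neither was called without mitochondrial peaks (exact adjusted p = 0.110 each). For V it was also not called among the 281 strongest peaks (exact adjusted p = 0.0972), and with peaks within 5 kb merged neither V (0.242) nor mitochondrial DNA (ratio 3.77, exact adjusted p = 0.408) was called. Merging joins the peaks of the 13794 bp mitochondrial genome into a single run, and the pooled regions were not merged. The loss of the mitochondrial call therefore follows by construction.

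**Figure D3:**
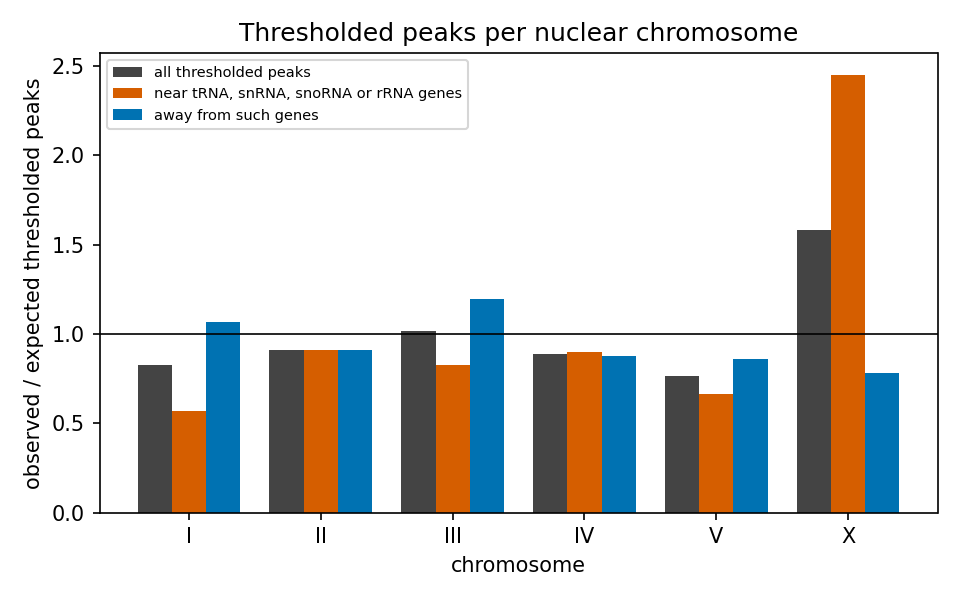
Observed over expected thresholded peaks (y axis, linear from 0) on each nuclear chromosome (x axis), for all peaks and for those near or away from tRNA, snRNA, snoRNA or rRNA genes. Expected numbers follow the pooled regions and the line marks a ratio of 1. On X the ratio is 1.58 for all peaks, 2.45 near such genes and 0.780 away from them.

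HND-1 belongs to a class of proteins that bind E-boxes, and 201 of the 562 summits (35.8%, Wilson interval 31.9% to 39.8%) had a CANNTG within 50 bp. The flanks had 28.4%, a difference of 7.38 percentage points (permutation p = 0.00317). Of the 10 classes, CAAGTG/CACTTG rose most, from 3.02% in the flanks to 8.01% in the centres (permutation adjusted p = 0.000900). CACATG/CATGTG (3.29% to 6.23%) and CAGCTG (0.890% to 2.85%) were also higher, and CAGATG/CATCTG, the class known for Hand proteins with their E protein partners, was lower (3.74% to 1.78%), with a permutation adjusted p of 0.0419 each. CAACTG/CAGTTG went from 3.91% to 6.58% without passing (permutation adjusted p = 0.0646), and passed in each replicate alone (0.0375 and 0.0396). The 6-mer test against 1 flank called partly other classes. There CAAGTG/CACTTG (exact McNemar adjusted p = 0.000144), CAGCTG (0.0168) and CAACTG/CAGTTG (0.0346) passed. CACATG/CATGTG (0.123) and CAGATG/CATCTG (0.297) did not. In replicates 1 and 2 alone, CAGCTG (permutation adjusted p = 0.239 and 0.359) and CAGATG/CATCTG (0.108 and 0.211) did not pass. Among the 281 strongest peaks none of the 4 called classes passed, with a permutation adjusted p of 0.0542 for CAAGTG/CACTTG, 0.0907 for CACATG/CATGTG and 0.813 for CAGCTG and CAGATG/CATCTG. With 100 bp on each side, CACATG/CATGTG (permutation adjusted p = 0.0629) and CAGCTG (0.103) did not pass, nor did CAGCTG with flanks at 600 bp (0.571), or CAGATG/CATCTG without mitochondrial peaks (0.0527). Against 1000 dinucleotide shuffles of the same centres, a number chosen after seeing the data, CAAGTG/CACTTG (permutation adjusted p = 0.03996), CACATG/CATGTG and CAGATG/CATCTG (0.04995 each) passed and CAGCTG (0.511) did not. CACCTG/CAGGTG, not called against the flanks, was lower than in these shuffles (1.96% against 3.97%, permutation adjusted p = 0.04995). With the planned 100 shuffles none of the 4 passed (permutation adjusted p from 0.0990 to 0.537), but so few could not let a single class pass after adjustment. The other classes did not pass against the flanks: CAAATG/CATTTG had 6.94% in the centres and 8.36% in the flanks, CAATTG 3.56% and 4.36%, CACCTG/CAGGTG 1.96% and 2.14%, CACGTG 1.60% and 1.51%, and CATATG 1.42% and 1.60%. In the 292 peaks away from tRNA, snRNA, snoRNA or rRNA genes, an E-box was present in 37.7% of centres against 25.3% of flanks (permutation p = 0.000260). CAAGTG/CACTTG reached 10.96% against 2.57% there (permutation adjusted p = 0.000200), and CAGCTG 4.45% against 0.685% (permutation adjusted p = 0.0173). CACATG/CATGTG turned there, at 2.05% of centres against 2.91% of flanks (permutation adjusted p = 0.752). Near such genes the overall shares were 33.7% and 31.7% (permutation p = 0.615). There CACATG/CATGTG rose from 3.70% to 10.7% and CAAATG/CATTTG fell from 8.70% to 3.33% (permutation adjusted p = 0.00780 each). Of the 223 tRNA genes with a thresholded summit, 186 had a sequence found more than once in the genome. Peaks at such copies are not independent, so p-values that include them, also those for all 562 peaks, may be too small. The overall excess depended on the comparison: with flanks at 600 bp it was 1.51 points (permutation p = 0.560), and with 100 bp on each side of the summit it was 2.58 points (permutation p = 0.340). Against 100 shuffles it was 3.65 points (permutation p = 0.0396), and against 1000 it was 3.46 points and did not pass (permutation p = 0.0559). In the 292 peaks away from the non-coding RNA genes it was 5.97 points against 100 shuffles and did not pass (permutation p = 0.0594), whereas with 1000 it did (permutation p = 0.0420).

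**Figure D4:**
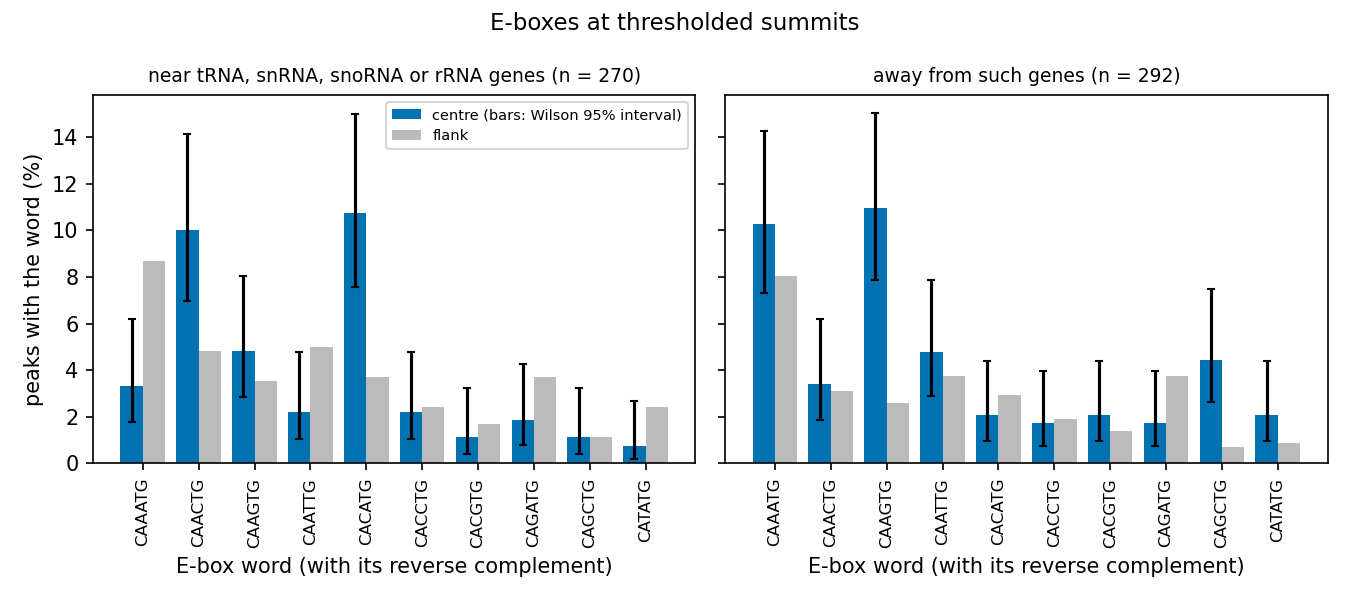
Share of peaks (y axis, percent) with each E-box class (x axis) within 50 bp of the summit, with Wilson 95% intervals, and in flanks 300 bp away, for the 270 peaks near tRNA, snRNA, snoRNA or rRNA genes (left) and the 292 others (right). CACATG stands above its flanks on the left, at 10.7%, and CAAGTG on the right, at 10.96%.

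Summits differed from their flanks in many other short words, and in base content. The G and C content was 48.7% in the centres and 35.2% in the flanks. Of all 6-mers tested, 727 passed the exact McNemar test after adjustment, 427 more frequent in the centres and 300 in the flanks. The most significant was ACCACT/AGTGGT, in 20.8% of centres and 1.96% of flanks (exact adjusted p = 3.01e-21). Of the 117 centres with this word, 96 belonged to the 270 peaks near tRNA, snRNA, snoRNA or rRNA genes (35.6% of those peaks). CGAACC/GGTTCG, a word of the tRNA gene's internal promoter, was in 16.9% of centres and 1.96% of flanks. AAAATT/AATTTT (16.19% of centres, 42.2% of flanks), AAAAAT/ATTTTT (23.5% and 49.3%) and AAATTA/TAATTT (8.01% and 27.4%) were rarer at summits. In the 270 peaks near the non-coding RNA genes 543 words passed, 316 more frequent in the centres and 227 in the flanks. Identical tRNA gene copies are counted there as separate peaks, so this number and that for all peaks may be too high. In the 292 peaks away from the non-coding RNA genes 176 passed (110 and 66), and the leading one, chosen after seeing the data, was CGCGCA/TGCGCG, in 19.9% of centres and 1.71% of flanks. The G and C content of these peaks was 46.5% in the centres and 35.1% in the flanks. The 6-mers were compared with flanks only, so how many of the calls follow from base content was not tested.

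Of the 17 gene lists, the ribosomal proteins were the 1 list that passed. A thresholded summit lay in the promoter window of 15 of 65 tested ribosomal protein genes (23.1%), against 357 of 7098 other genes (5.03%), an odds ratio of 5.66 (interval 2.92 to 10.4, Fisher's exact adjusted p = 1.32e-05). The strongest were rpl-3 (summit III:3867560, 294 bp upstream, signal 368, ranks 73 and 180 in replicates 1 and 2), rpl-20 (IV:4750060, signal 308), rpl-15 (IV:654920, signal 302), rps-26 (I:14759514, signal 279), rps-28 (IV:1659249, signal 274) and rps-20 (I:14469348, signal 213), all intergenic. The summit assigned to rps-26 also lay within 200 bp of a snoRNA gene. It was 416 bp upstream of rps-26 but 41 bp from the 5′ end of another protein-coding gene. Against random lists matched on upstream intergenic length the ratio was 3.07 (permutation adjusted p = 0.00680). When each peak was given only to its nearest 5′ end, the odds ratio was 3.57 and the list no longer passed (exact adjusted p = 0.0577). With all protein-coding genes as background the odds ratio was 13.04.

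Regulators and structural genes of the tissues in which HND-1 is known to act had no thresholded summit in their promoter windows. This was so for 0 of 12 tested body wall muscle regulators, 0 of 38 muscle structure genes and 0 of 11 somatic gonad precursor genes, with Wilson upper limits of 24.2%, 9.18% and 25.9%. The same count of 0 was found for 8 pharynx genes, 8 intestine genes, 21 epidermis genes, 16 basic helix-loop-helix genes and 6 T-box genes, with upper limits of 32.4%, 32.4%, 15.5%, 19.4% and 39.03%. None of these lists passed the test (exact adjusted p = 1 for each), and shares up to these limits stayed open. Of all 7163 tested genes only 5.19% had such a summit. Random lists matched on upstream length held on average 0.519 such genes for body wall muscle regulators, 1.25 for muscle structure and 0.468 for somatic gonad precursors. The counts of 0 therefore do not show that the peaks avoid these genes. The counts of 0 depended on the assignment. By nearest 5′ end the odds ratios were 0.459 for muscle structure, 0.599 for epidermis and 0.831 for basic helix-loop-helix genes, so these lists then had a member with a peak. With the 2000 bp window epidermis was at 0.732. The other lists with a count of 0 stayed at 0 in both, and none passed. Among 48 embryonic fate regulators, 2 had a summit: daf-19, an RFX factor of ciliated neurons (II:10169514, signal 154), and lpd-2 (I:6252977, signal 128). The germline list had mex-1, an RNA-binding protein of early blastomeres (II:11967725, signal 217), as 1 of 28, and the neuron list syd-2, a presynaptic scaffold (X:10555630, signal 140), as 1 of 25. His-67 and his-68 shared a summit between them (I:9989010, signal 197) and were 2 of 32 histone genes. The chaperone genes hsp-60 (III:1619121, signal 234) and hsp-1 (IV:17278603, signal 213) were 2 of 14 heat shock and stress genes (odds ratio 3.05, interval 0.331 to 13.8). The single members of the homeobox list (ceh-2, 1 of 23), the nuclear receptors (nhr-255, 1 of 78) and the cuticle collagens (col-185, 1 of 32) had their summits inside one of the non-coding RNA genes. For all of these lists the exact adjusted p was 1.

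At the fixed loci no promoter window held a thresholded summit. The best pooled region in the window ranked 8538 for hlh-1 (the MyoD homologue of body wall muscle), 8465 for unc-120, 6988 for pal-1 and 2446 for unc-119, and hnd-1, ehn-3 and hlh-2 had none. For hlh-2, which encodes the E protein, a pooled region 1140 bp upstream (I:7195060), outside the window, had rank 572, with 823 and 448 in replicates 1 and 2. Around hnd-1 on X, the gene carried by the transgene, the 40 kb window held 1 pooled region, against a median of 11 over 2509 windows, of which 97.8% held as many or more. The list of replicate 1 had 1 region there and that of replicate 2 had 4. That region was thresholded, at X:11666614-11667017, 17745 bp upstream of hnd-1 and 311 bp from the 5′ end of noca-2 (signal 139, ranks 606 and 392). Around unc-119 on III there were 19 pooled regions and 0 thresholded peaks, and 18.3% of windows held as many or more pooled regions.

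On the older build ce10 the thresholded list held 767 peaks, 205 more than on ce11, while both pooled lists held 30000 regions with nearly the same signals, up to 2976. The ce10 list reached down to a signal of 107, against 126 on ce11, and 561 of its peaks had a signal at or above the ce11 minimum. The mitochondrial count was 15 on both builds. Chromosome X had 154 thresholded peaks on ce10 and 121 on ce11, and chromosome I 179 and 115.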

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

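Alternatives that set aside mitochondrial peaks or peaks near tRNA, snRNA, snoRNA or rRNA genes (called the small RNA genes here), and the 1000 shuffles, were chosen after seeing the data; the others were not. Unless given, the cause was not tested. Replicate agreement stayed above its shifts in all 10 alternatives run, from 33.8% (strongest 10000) and 36.4% (5000) to 76.4% (500). Promoter shares (37.4% to 90.6%, the latter with windows of all annotated genes) and non-coding RNA shares (44.3% to 63.0%) stayed past the threshold in all of theirs. The number of peaks was 281 when only the stronger peaks were kept and 292 without peaks near the small RNA genes, by construction. The overall E-box excess did not pass with 100 bp each side (2.58 points), flanks at 600 bp (1.51), 1000 dinucleotide shuffles (3.46) or 100 shuffles without the small RNA genes (5.97, permutation p = 0.0594); it passed against the planned 100 shuffles of all peaks (3.65, p = 0.0396) and against 1000 without the small RNA genes (permutation p = 0.0420). The 6-mer count was 176 without the small RNA genes and 543 in the 270 peaks near them. For gene lists, 0 passed by nearest 5′ end.

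The chromosomes called numbered 6 by length, 3 on ce10 and among the stronger 281, 2 and 3 with each replicate alone, 1 without mitochondrial peaks, 1 without the small RNA genes and 2 with peaks within 5 kb merged, where the mitochondrial call was lost by construction (ratio 3.77). Without the small RNA genes the ratio of chromosome X turned to 0.780 and that of I to 1.07, and by length I turned to 1.36. The ratio of III, not called, was 0.963 among the stronger 281, and 0.897 to 0.995 with each replicate alone; by length III (1.23) and IV (0.755) passed.

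E-box classes that turned were uncalled, except CACATG at -0.856 points without the small RNA genes. There CAAATG was at 2.23, CAATTG at 1.03 and CATATG at 1.199. With replicates 1 and 2 alone, in that order, CAATTG was at -0.445 and 0.267, CACGTG at -0.267 and 0.356, and CATATG at 0.445 and -0.890. CACGTG was at -0.445 with 100 bp each side, -1.33 with flanks at 600 bp and -0.728 against shuffles, which put CAATTG at 0.151 and CATATG at 0.222. Turned odds ratios of uncalled lists were 1.56 (germline), 0 (histones) and 1.36 (collagens) among the stronger 281, 0.977 (histones) and 1.00 (collagens) with the 2000 bp window, 1.02 (fate regulators) against all genes, 1.55 (neurons) and 1.43 (collagens) by nearest 5′ end, and, as length-matched ratios, 1.10 (fate regulators), 0.889 (histones) and 1.03 (homeobox). Of values for single chromosomes, words or lists, 244 kept direction and side of the threshold, and 29 turned direction, some of them losing their call. Among the others, which kept direction, 28 no longer passed and 4 newly passed. Depth is unknown, which limits what an absent region can show.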

Other observations

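The stretch around the hnd-1 gene was looked at after its count of regions had been seen. No pooled summit lay between X:11666816 and X:11725985, a stretch of 59.2 kb with 15 protein-coding genes inside it. Of 4081 gaps between neighbouring pooled summits on X, 9 were as long, and the median gap was 2.22 kb. The gap was 57.5 kb in replicate 1 and 47.5 kb in replicate 2, where 2 gaps on X were as long in each list. Whether extra transgene copies change the control there was not tested.

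Of the tests below, those with 1000 shuffles and all values with peaks near tRNA, snRNA, snoRNA or rRNA genes set aside were chosen only after the overall results had been seen. No expression data or other tagged strain was used here.

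For the thresholded peaks at tRNA and snoRNA genes, reads shared between identical gene copies are argued against as the whole source: of 505 such genes whose sequence occurs once in the genome, 18.2% had a thresholded summit within 200 bp (Wilson interval 15.1% to 21.8%), although copies that differ by a few bases were not considered. For tRNA genes the share was 22.8% of 162 with a sequence found once and 39.4% of 472 with more copies (Fisher's exact p = 0.000128), so sharing may still add to the signal. High transcription of the bound genes stays a candidate that the test could not decide. With peaks near tRNA, snRNA, snoRNA or rRNA genes set aside, ribosomal protein genes had an odds ratio of 6.398 (interval 3.23 to 11.9). This met the condition set beforehand, but ribosomal protein genes only stand in for transcription. By nearest 5′ end their list did not pass among all peaks (Fisher's exact adjusted p = 0.0577). The value describes other peaks and is close to the 5.66 found for all peaks. It therefore cannot decide the source of the peaks at tRNA and snoRNA genes. Binding of HND-1 through E-boxes stays open, since 33.7% of centres at these sites had an E-box, between the mean (32.6%) and the highest of 100 shuffles. CACATG/CATGTG was more frequent there (10.7%) than in any of 1000 shuffles (highest 8.89%). So was CAACTG/CAGTTG (27 of 270 centres, highest 9.63%, permutation adjusted p = 0.00999 each). The latter did not pass against the flanks (4.81%, permutation adjusted p = 0.0546). Of the 223 tRNA genes with a thresholded summit, 186 had a sequence found more than once, so these centres are not independent. The range of the shuffles may therefore be too narrow. This comparison cannot decide whether base composition accounts for these words. Whether these words belong to the RNA genes' own sequence was not tested.

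The excess of peaks on chromosome X may follow the tRNA genes there. In peaks more than 200 bp from tRNA, snRNA, snoRNA or rRNA genes the ratio of observed to expected peaks on X was 0.780 (exact binomial p = 0.147). Of the tRNA genes on X 35.9% had a thresholded summit, against 34.8% on I, 42.1% on II, 45.3% on III, 38.03% on IV and 21.8% on V. No biological explanation specific to X was tested.

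The E-box excess at summits is not accounted for by the sequence of the non-coding RNA genes alone, since it was 12.3 percentage points in peaks away from them. Whether base composition accounts for the overall excess stays open: the observed 35.8% lay within the range of 100 dinucleotide shuffles of the same centres (highest 35.9%), but above their mean of 32.1% (permutation p = 0.0396). With 1000 shuffles the permutation p was 0.0559 for all peaks and 0.0420 for those away from the non-coding RNA genes. Base composition does not account for CAAGTG/CACTTG in peaks away from those genes, where 10.96% of centres had the word and the highest of 1000 shuffles was 8.90% (permutation adjusted p = 0.0200 over 10 classes). That this word marks direct binding of HND-1 or of a partner remains a hypothesis, since it was picked as the leading class and tested on the same peaks.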
